A study of Homo sapiens with 6 samples.

How the data were processed

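Histone H4 acetylated on both lysine 5 and lysine 8 (H4K5acK8ac) was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) with a mouse monoclonal antibody made by the submitters. The series has 6 samples: 2 libraries of GM12878, a lymphoblastoid line made by transforming B cells with Epstein-Barr virus, 2 of K562, a line from a chronic myelogenous leukaemia, and 2 input samples, 1 per line. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sheared with a Covaris instrument and libraries were made on a Mondrian system. The analysis used the 4 peak lists of the ChIP libraries; the inputs were not analysed here as samples of their own. Groups and replicate numbers were taken from the sample titles, which match the cell line given among the characteristics. The free-text descriptions of all 4 ChIP samples instead name H23 cells, and the protocol text names H23 chromatin, so the labels conflict on this point. Nothing in the labels says whether replicates came from separate cultures, so the spread between them may be technical.

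Reads were aligned with BWA to hg19 and peaks were called with MACS2, per the submitters' processing notes; versions and options are not given in the sources used here. Each library has its own list, so peaks were called per sample and not on pooled replicates. The deposited lists hold for each peak its position, a score, a fold enrichment, a −log10 p and a −log10 q, and the offset of its summit. The deposited score is 10 times the −log10 p cut to a whole number. The fold is a ratio of pileup to local background, as the authors' peak caller gave it, and was used only to describe, rank or filter peaks within its own list. The lowest deposited −log10 p in a list lay between 2.00 and 2.04, so the lists reach down to weak peaks. Between 5.36% and 8.68% of a list had a q above 0.05.

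Peaks on chromosomes 1 to 22 and X were used, which makes 23 chromosomes. No peaks overlapped within a list. Library pairs were compared by the Jaccard index of covered bases and by the percentage of the peaks of one library touched by at least 1 bp of the other. Both were set beside the mean of 20 seeded circular shifts of the second list along each chromosome. All 4 lists were merged into regions. A region was called shared when all 4 libraries had a peak in it, GM12878-only when both GM12878 libraries and no K562 library had one, and K562-only in the mirror case. Domains were bases covered in both replicates of a line, joined over gaps of up to 3 kb and ranked by covered bases. No test over libraries was run: a permutation of the labels of 4 libraries in pairs cannot give a p below 0.333, and no model of values per library was fitted. The regions named are taken from the 10 of each class whose lowest percentile of fold within the lists was highest, not all of which are given, and the domains are the 5 widest of each line, by rules fixed before the data were examined for the case that no annotation of the files' build could be used.

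No hg19 genome or annotation was used here. The reference table at hand is of another build and its coordinates were not applied. The planned location of regions relative to genes, the promoter calls, the 30 gene lists and the motif counts were therefore not run, and which genes lie in an interval was not looked up. Coordinates are those of the deposited lists (hg19), counted from 1.

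The lists hold no read totals. For a peak with pileup k over local background L, MACS2's fold is (k + 1) / (L + 1) and its p is the Poisson chance of more than k reads, so k and L can be solved for. A whole-number k matched the deposited −log10 p within 0.001 for between 99.4% and 99.97% of peaks per list. The lowest L of a list is its genome-wide background. Divided by the narrowest peak width, taken as the caller's fragment length, it gives the relative depth in reads per kb: 6.60 and 4.98 for GM12878 replicates 1 and 2, and 6.94 and 11.3 for K562 replicates 1 and 2. The factor per list of which the commonest higher values of L were best described as multiples was then sought, as a scaled control library gives. The share of values that are such multiples is not given. The control depth that this factor implies was 13.2 reads per kb in both GM12878 lists and 11.6 in both K562 lists. Genome-wide depth in reads is unknown, since the genome size used by the caller is not stated.

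For the closing section, windows of 500 kb with at least 5 line-only regions were tested with Fisher's exact test, two-sided, against the rest of the genome, with Benjamini-Hochberg adjustment. Regions are not independent replicates, so these p values describe the 4 lists. The class of neighbouring line-only regions was tested with 100000 permutations of class within chromosomes. For the longest interval without a K562 peak, K562 presence was permuted 100000 times over the regions with a GM12878 peak within chromosomes, region by region and in blocks of 10 consecutive ones, with regions of K562 alone kept in place. Each permutation gave its own longest interval. On simulated lists, 100% of 48681 regions were put in their class and 20 of 20 seeded windows were recovered. With random labels 0 of 3112 windows were called, and the pileup was recovered for 100% of 19649 simulated peaks. The simulated regions lay apart on a regular grid, and simulated folds and p values came from the formula that was then solved. These results therefore check the code and not the rate of false calls in clustered lists. Alternatives were peaks with a −log10 q of at least 5, lists cut to the 44824 strongest peaks, presence by coverage of at least 50% of a region or peak, domains joined over gaps of up to 12.5 kb, each replicate left out in turn, and, added after seeing the data, 1 library taken from each line. Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.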

Results

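The data are 4 peak lists of H4K5acK8ac, a doubly acetylated form of histone H4, from the B lymphoblastoid line GM12878 and the myelogenous leukaemia line K562, with 2 libraries per line. GM12878 replicates 1 and 2 had 90230 and 88079 peaks, which covered 66.4 and 60.6 Mb. K562 replicates 1 and 2 had 62539 and 44824 peaks, which covered 42.9 and 26.2 Mb. The median peak was 470 and 439 bp wide in the GM12878 lists and 456 and 418 bp wide in the K562 lists. The authors' fold enrichment had a median of 4.36 and 4.32 within the GM12878 lists and of 4.72 and 4.07 within the K562 lists. The relative depth recovered from the lists was highest in K562 replicate 2, at 11.3 reads per kb, and lowest in GM12878 replicate 2, at 4.98 reads per kb. The shortest list therefore came from the deepest library.

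The first comparison asks how far peaks recur between replicates and between the lines. The Jaccard index of covered bases was 0.596 between the GM12878 replicates and 0.513 between the K562 replicates. The 4 pairs across the lines gave 0.179 ± 0.0161 (SD over 4 pairs, which share libraries), with a range of 0.162 to 0.194. Circular shifts gave means between 0.00624 and 0.0114. Each line's replicates thus shared more covered bases than any pair across the lines, and pairs across the lines shared more than shifted lists. Of the peaks of K562 replicate 2, 85.4% were touched by replicate 1, whereas 52.2% of the peaks of replicate 1 were touched by replicate 2. In GM12878 the corresponding values were 74.8% and 69.4%.

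**Figure D1:**
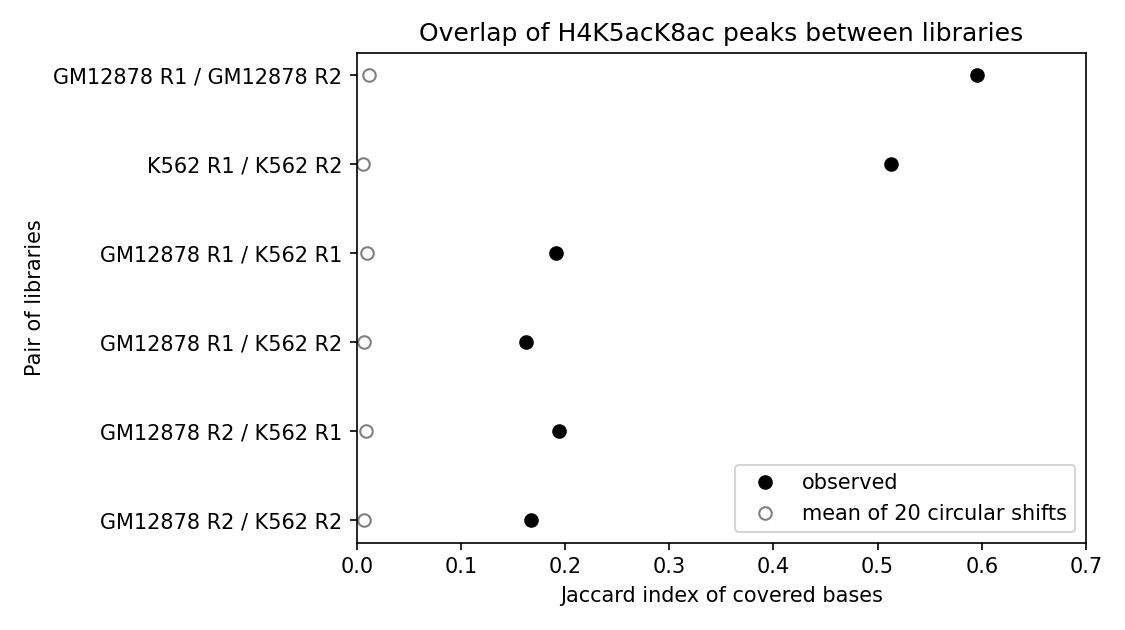
Jaccard index of covered bases (x axis) for the 6 pairs of libraries (y axis). Filled points are observed values and open points the mean of 20 circular shifts; the within-line pairs lie at 0.596 and 0.513 and the 4 pairs across lines between 0.162 and 0.194.

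The second comparison asks which regions carry the mark in both lines and which in 1 line. Merging the lists gave 143480 regions, of which 15186 were shared by all 4 libraries, 34687 were GM12878-only and 13500 were K562-only. The remaining 80107 regions were mixed or not found in both replicates, and 50.3% of all regions were found in 1 library alone. The class counts move with the rule. Shared regions numbered 7739 when at least 50% of a region had to be covered. GM12878-only regions numbered 59173 without GM12878 replicate 2, and K562-only regions 35611 without K562 replicate 2. Of the 54010 regions found in both GM12878 replicates, 28.1% were also in both K562 replicates and 64.2% were in neither. Of the 30509 regions found in both K562 replicates, 49.8% were in both GM12878 replicates and 44.2% in neither. This asymmetry moves with list length: K562 touched a mean of 25.1% of GM12878 peaks and GM12878 a mean of 42.45% of K562 peaks over the 4 pairs, against 37.3% and 39.0% with lists of equal length. Shared regions were wider, with a median of 1545 bp against 751 bp for GM12878-only and 703 bp for K562-only regions. Part of this follows from merging, since a shared region joins peaks of 4 libraries and a line-only region peaks of 2. Shared regions also ranked higher within each list, although a wider region has more peaks to take the strongest from. In GM12878 replicate 1 the strongest peak of a shared region had a median percentile of 84.8, against 59.3 for GM12878-only regions. In K562 replicate 1 the percentiles were 83.9 for shared and 65.0 for K562-only regions. The ratio of GM12878-only to K562-only regions was 2.57. It fell to 1.24 with lists of equal length. It was 0.983 without K562 replicate 2, where a K562-only region then needed 1 library, while a GM12878-only region still needed both and had to be absent from 1. With 1 library taken from each line, a comparison added after seeing the data, the 4 pairs gave 1.46 to 3.18.

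The GM12878-only region that ranked highest in both replicates lay on chromosome 21 at 44770016 to 44776871, with the authors' fold enrichment at 101 and 97.5 in replicates 1 and 2. A second region of the same class lay nearby on chromosome 21, at 44817221 to 44822625, with folds of 70.5 and 63.6. The next in rank were on chromosome 8 at 142254315 to 142256871, with folds of 92.2 and 85.1, and on chromosome 14 at 106041620 to 106045069, where the lower of the percentiles in both lists was 99.97. As background, the immunoglobulin heavy chain genes, which B cells rearrange and express, lie near the end of the long arm of chromosome 14. Which genes lie in this region or in the other named regions was not looked up. Chromosome 5 held 2 of the 10, at 366751 to 379762 and at 423714 to 425694, with folds of 78.8 and 74.6 in the first and of 71.7 and 70.5 in the second. The others lay on chromosomes 7, 4, 19 and 2.

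Among K562-only regions the highest in rank lay on chromosome 14 at 102174651 to 102184579, with folds of 98.4 and 57.3 in K562 replicates 1 and 2. It was followed by chromosome 7 at 150758334 to 150760712, with 86.5 and 50.8, and chromosome 1 at 207193070 to 207200007, with 81.5 and 50.6. Regions on chromosome 19 at 29092652 to 29101964 and chromosome 6 at 68590778 to 68600689 were 9313 and 9912 bp wide. A further K562-only region of the 10 was on chromosome 14, at 101236096 to 101240285. The shared regions with the highest lowest percentile were on chromosome 11 at 65183443 to 65192662, on chromosome 19 at 41769907 to 41772838 and on chromosome 9 at 86593856 to 86597037. Their folds were 80.2 and 86.0, 100.5 and 106.2, and 77.2 and 77.4 in the GM12878 replicates.

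The third comparison concerns wide domains, the stretches covered in both replicates of a line. GM12878 had 33193 domains, of which 297 held at least 10 kb of covered bases, and K562 had 22681, of which 14 did. These values move when a line's domains are taken from 1 replicate alone. Without GM12878 replicate 1 or 2, 426 and 530 GM12878 domains reached 10 kb, and the widest GM12878 domain had 84.4 or 60.8 kb covered. Without K562 replicate 1 or 2, 16 and 86 K562 domains reached 10 kb. A K562 domain needs coverage in both replicates, and K562 replicate 2 covered 26.2 Mb, the least of the 4 libraries. Domains were not taken from lists of equal length or from stricter peaks, so how far list length sets the contrast between the lines was not tested. The widest GM12878 domain, on chromosome 14 at 22940979 to 23010292, had 55.3 kb covered; K562 peaks of either replicate covered 1.81 kb within its span. The next lay on chromosome 22 at 23241829 to 23298101, with 46.4 kb, and on chromosome 12 at 11870132 to 11937241, with 42.97 kb and no K562 peak. As background, the immunoglobulin lambda genes lie on the long arm of chromosome 22. Which genes lie in this domain or in any other, the widest included, was not looked up. Domains on chromosome 9 at 37366020 to 37418135 and chromosome 1 at 12098935 to 12142622 had 38.8 and 31.9 kb covered.

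The widest K562 domain was on the X chromosome at 65205571 to 65240918, with 23.9 kb covered. GM12878 peaks of either replicate covered 9.90 kb within it. The domain on chromosome 6 at 147195493 to 147224251 had 20.1 kb covered and no GM12878 peak. Those on chromosome 6 at 37136705 to 37161893 and chromosome 20 at 23112177 to 23143239 had 18.6 and 18.4 kb. The domain on chromosome 11 at 65237973 to 65268471 had 18.0 kb, and GM12878 peaks covered 17.7 kb within it. Of the 100 widest domains, 24 in GM12878 held no K562 peak and 60 held peaks of both K562 replicates. In K562, 17 held no GM12878 peak and 71 held peaks of both GM12878 replicates. These counts do not give the extent of overlap. Bases covered in both replicates of the other line, within the span of such a domain, were set against the domain's own covered bases. The median was 2.95% for these GM12878 domains and 14.4% for these K562 domains. The span includes joined gaps and the covered bases do not, so these values compare amounts and are not shares of a domain. Over all domains, 37.2% in GM12878 and 55.6% in K562 held peaks of both replicates of the other line. The 100 widest had at least 14729 covered bp in GM12878 and 6266 in K562, so the sets differ in width. With domains joined over wider gaps, 14 and 8 of the 100 widest held no peak of the other line. Peaks of both its replicates were held by 73 and 88, and the medians were 6.36% and 48.3%.

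**Figure D2:**
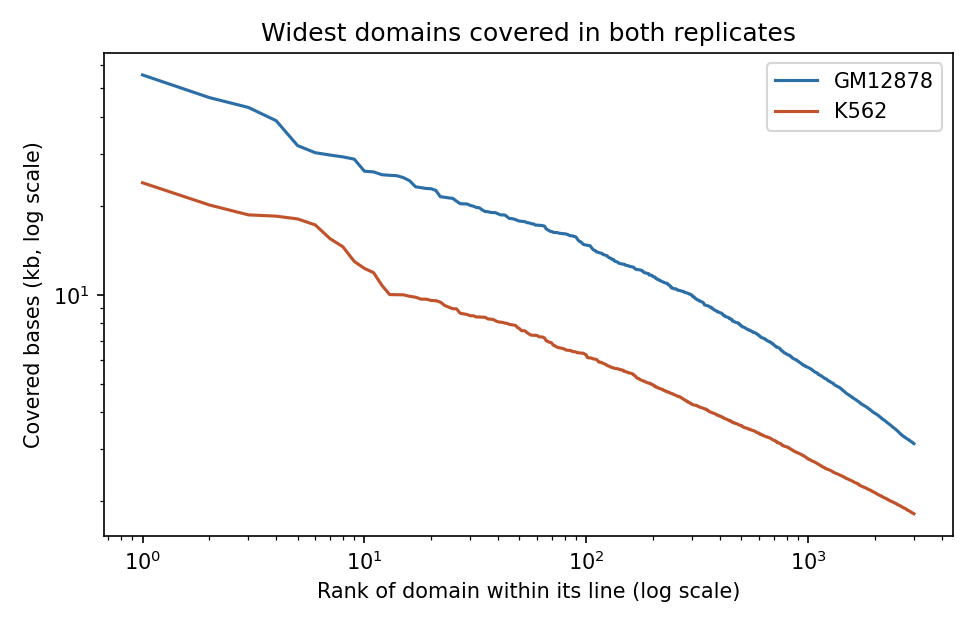
Covered bases per domain in kb (y axis, log scale) against the rank of the domain within its line (x axis, log scale), for GM12878 and K562. The curves start at 55.3 kb in GM12878 and at 23.9 kb in K562.

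The last comparison sets the share of covered bases on each chromosome in K562 against GM12878. Shares are of each library's own total. The K562 share was lowest relative to GM12878 on chromosome 13, at 1.29% against 2.10%, a ratio of 0.617. The 4 pairings of replicates gave 0.590 to 0.644. Chromosome 14 had a ratio of 0.657 (0.621 to 0.693), chromosome 18 of 0.726 (0.719 to 0.734) and chromosome 22 of 0.752 (0.714 to 0.792). In the lists as deposited, the ratio was highest on chromosome 19, at 1.26 (1.21 to 1.30), followed by X at 1.17 (1.10 to 1.25), chromosome 6 at 1.17 (1.12 to 1.21) and chromosome 7 at 1.16 (1.11 to 1.21). This order is not stable. X and chromosome 19 were at 1.25 and 1.17 with lists of equal length, and at 1.24 and 1.23 with stricter peaks. Every pairing of replicates lay on the same side of 1 for 21 of the 23 chromosomes, all but 3 and 21, so this does not set these 8 apart. No test over libraries was run; a permutation of the labels of 4 libraries cannot give a p below 0.333.

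**Figure D3:**
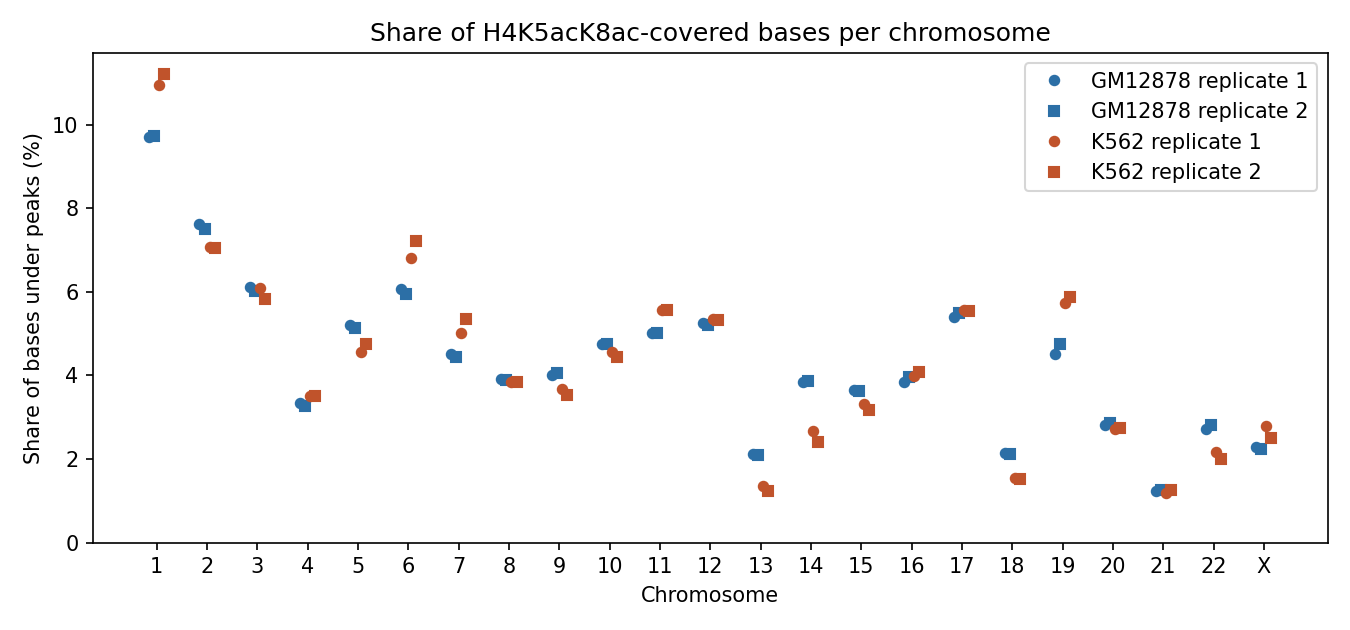
Share of covered bases in % (y axis) per chromosome (x axis), with 1 point per library: GM12878 in blue and K562 in orange, replicate 1 as circles and replicate 2 as squares. On chromosome 13 the GM12878 mean is 2.10% and the K562 mean 1.29%.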

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

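Peaks on the mitochondrial sequence enter none of the comparisons. K562 replicate 1 lists 9 of them, and the other 3 libraries list 0. This was picked out as a signal outside the main measurement in 1 library; mitochondrial DNA carries no histones, and no explanation was tested.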

How the results depend on the processing

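The alternatives without a replicate for domains and chromosome shares, and those for windows, neighbours, intervals, named regions and 1 library per line, were chosen after seeing the data. Of 179 alternative values, 115 were called the same and 1 turned in direction, by rules that differ between kinds of value. Counts and the ratio of line-only regions had to stay within 1.5 times the main value. Chromosome ratios and means of pairs across lines had to stay within 1 SD. Single values, such as a Jaccard index within a line, had to be unchanged, and the share of same-class neighbours had to keep a permutation p under 0.05. The 115 include the named regions, chosen as the strongest of their class, which kept it throughout. The tally is therefore no single measure of stability. The cause of the other values was not tested unless the alternative itself gives it. No paired analysis was run, as no result here comes from a test over libraries; for chromosome shares, the same-numbered pairs are among the pairings given. A region present in both same-numbered GM12878 libraries and absent from their K562 partners is by construction a GM12878-only region. Location relative to genes, promoter calls, gene lists and motifs were not run under any setting, as no hg19 annotation or genome was used here. Without totals of reads, depth limits what can be said of absent peaks.

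With stricter peaks the lists held 43646, 37711, 32874 and 21858 peaks (GM12878 replicates 1 and 2, then K562), by construction fewer. The Jaccard index was 0.669 within GM12878, 0.533 within K562 and 0.196 between lines. Touched peaks were 76.0% and 90.1% for GM12878 replicates 1 and 2 within their line, 58.3% and 98.2% for K562, and across lines 33.7% of GM12878 and 50.3% of K562 peaks. There were 17318 GM12878-only and 7325 K562-only regions, and the chromosome 13 ratio was 0.648.

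With lists of equal length each held 44824 peaks. The Jaccard index was 0.674 within GM12878, 0.562 within K562 and 0.198 between lines. Touched peaks were 81.1% and 84.8% within GM12878, 68.1% and 81.5% within K562, and 37.3% of GM12878 and 39.0% of K562 peaks across lines. There were 18115 GM12878-only regions, and their ratio to K562-only regions was 1.24. Share ratios were 0.651 for chromosome 13, 0.751 for 18, 0.710 for 22, 1.25 for X and 1.17 for 19.

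When at least 50% had to be covered, touched peaks were 60.6% and 68.0% within GM12878, 42.2% and 82.8% within K562, and 19.7% of GM12878 and 37.1% of K562 peaks across lines; shared regions numbered 7739. With domains joined over the wider gaps, GM12878 had 21873 domains, 705 of at least 10 kb, the widest with 83.5 kb; K562 had 70 of at least 10 kb, the widest with 30.3 kb.

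With each replicate left out in turn, GM12878-only regions ran from 35021 to 59173 and K562-only regions from 14274 to 35611, against 34687 and 13500 with all libraries. Their ratio ran from 0.983 without K562 replicate 2, where it turned, to 4.15 without GM12878 replicate 2. Leaving out a replicate asks for presence in 1 library of its own line and for absence from 1 library where the other line's regions are called, so by construction neither count can fall; the count of the replicate's own line rose more each time. With 1 library from each line the ratio was 1.61 and 1.46 for GM12878 replicates 1 and 2 against K562 replicate 1, and 3.18 and 2.90 against K562 replicate 2. Domains of at least 10 kb ran from 426 to 530 in GM12878 and from 16 to 86 in K562, the widest from 60.8 to 84.4 kb and from 24.7 to 30.1 kb, and K562 domains from 27504 to 35021.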

Other observations

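Except where stated, the tests in this part were chosen after their results, or values bearing on them, had been seen. Neighbouring line-only regions tended to be of the same class. Of 48164 pairs of neighbouring line-only regions on a chromosome, 80.0% were of the same class, against a mean of 59.95% when classes were permuted within chromosomes (permutation p = 1e-05, one-sided, the smallest that 100000 permutations can give). The value was 73.6% with lists of equal length. Regions join only peaks that overlap, so neighbours can be pieces of 1 wider acetylated locus, and the permutation moved each piece singly. The permutation p therefore does not measure grouping across separate loci. Of 3018 windows of 500 kb tested, 265 leaned to GM12878 and 418 to K562 at an adjusted p under 0.05 (Fisher's exact test, Benjamini-Hochberg). The window tests also count each piece of a wider locus as a region of its own, so their p values share this limit. GM12878-only regions made up 72.0% of all line-only regions, so a call towards K562 needed fewer regions than a call towards GM12878. The numbers of windows called for each line therefore cannot be set against each other. With stricter peaks these counts fell to 57 and 149, and without K562 replicate 2, where K562 presence needs 1 library, they were 643 and 589. The window leaning most to GM12878 was on chromosome 14 from 68.5 to 69 Mb, with 77 GM12878-only regions against 1 K562-only (Fisher's exact test, adjusted p = 8.88e-08). Windows on chromosome 18 from 56 to 56.5 Mb and from 11 to 11.5 Mb held 49 and 47 GM12878-only regions and 0 K562-only. The window leaning most to K562 was on chromosome 3 from 45 to 45.5 Mb, with 36 K562-only against 4 GM12878-only regions (Fisher's exact test, adjusted p = 9.58e-13). Others lay on X from 11 to 11.5 Mb, with 27 against 0, and on chromosome 11 from 5 to 5.5 Mb, with 22 against 0 (Fisher's exact test, adjusted p = 1.78e-12 and 2.97e-10). As background, the beta-like globin genes, used by erythroid cells, lie near the tip of the short arm of chromosome 11; which genes lie in the window was not looked up.

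Recurrence in the other line rose with strength. Among regions found in both GM12878 replicates, ordered by the lower of their percentiles, the weakest 10% were in both K562 replicates in 7.20% of cases and the strongest 10% in 67.6%. Among regions of both K562 replicates the values in GM12878 were 23.8% and 88.5%. A region that merges more peaks has more to take its percentile from, which can add to this rise by construction.

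The K562 lists were shorter, and K562-only regions fewer, than those of GM12878; lower depth of K562 replicate 2 is argued against, since its recovered reads per kb were 1.83 times the mean of the other 3 libraries. Folds at shared regions were compared first, which gave a lower fold in K562 replicate 2 than in replicate 1 in 97.8% of them, but a fold belongs to its own list, so this decides nothing. A rank test within 1 list was then set, with that outcome and the touched shares known but before its own value was. A peak of K562 replicate 1 touched by replicate 2 ranked above an untouched one in 90.3% of pairs, so replicate 2 missed mainly weak peaks. The same held in the other lists, each against the other replicate of its line. The values were 84.9% and 84.6% for GM12878 replicates 1 and 2 and 84.3% for K562 replicate 2. As every list gave a high value, the rank test cannot say why the K562 lists were shorter. With lists of equal length the ratio of GM12878-only to K562-only regions was 1.24, a value with no replicate spread; forms of a list-length test with a bound set once the value was known, or with a range fixed by leaving out a replicate of 1 line, were put aside. List length, a weaker enrichment in K562 replicate 2 and a biological difference between the lines stay open.

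Chromosome shares may follow the DNA copy number of K562. The local background recovered at shared regions served as a stand-in for copy number. By construction it cannot lie below the genome-wide background of its list, so it can understate a loss of DNA. Between 18.2% and 28.0% of a list's peaks with a recovered background lay at that floor. The stand-in was taken as the ratio of K562 to GM12878. Over the 23 chromosomes, which are not independent samples, Pearson's r between this ratio and the ratio of shares was 0.371 (permutation p = 0.0757) and Spearman's rho 0.242 (permutation p = 0.262), both two-sided, in 1 relation examined. Without the chromosomes farthest from the median background ratio, 21 and 22, Pearson's r was 0.603 (permutation p = 0.00326) and rho 0.400 (permutation p = 0.0733). The outcome thus turns on those chromosomes, and copy number and a difference in acetylation cannot be told apart here: chromosomes 13 and 14 had low background ratios of 0.875 and 0.878, while chromosome 22 had a high one, of 1.38, with a share ratio of 0.752.

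The longest interval without a K562 peak that held at least 10 regions of both GM12878 replicates was on chromosome 9 from 20684810 to 26892063, a length of 6.21 Mb with 38 such regions. As background, K562 is known to have lost DNA of band 9p21; where that loss lies on hg19 was not looked up. With K562 presence permuted in blocks of 10 regions, 7 of 100000 permutations had a longest such interval of that length or more (permutation p = 8.00e-05, one-sided), and permuted region by region 0 had. This argues against a chance gap made of short runs of absence only, since blocks of 10 break up longer runs. Such runs exist: K562-free intervals on chromosomes 18 and 3 held 64 and 53 such regions over 0.851 and 0.546 Mb. The chromosome 9 interval stands out in length and not in number of regions, so an ordinary K562-free run where GM12878 peaks are sparse is not excluded. Reads that cannot be placed are argued against, since GM12878 had 9.02 peaks per Mb there, 34.3% of the median window. Silent chromatin with the DNA kept and loss of the DNA cannot be told apart, because only 1 other window with at least 10 GM12878 regions lacked reproducible K562 regions (it held 3 single-replicate ones, so the share without any was 0%); without K562 replicate 1 or GM12878 replicate 1 the longest such interval was instead on chromosome 13 or X, at 7.51 and 6.85 Mb.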
